A study of Arabidopsis thaliana with 18 samples.

How the data were processed

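Seeds of the Arabidopsis thaliana accessions Col-0 and C24 were compared at 3 stages, 8-9, 10-11 and 12-13 days after flower opening, with 3 arrays per accession and stage (18 arrays in 6 groups). Per the labels, each array was made from seeds dissected out of a pool of 48 siliques, 8 from each of 6 plants, and 6 plants per accession were grown in each of 2 experiments. A group of 3 pools therefore drew 18 times on 12 plants, so that pools shared plants, and the p-values measure the spread between pools rather than between independent plants. The 3 stages of an accession drew on the same 12 plants, so that stages shared plants too, which the model did not take into account. Plant, experiment and hybridisation batch of an array were not given in the sources used here, and no batch was tested.

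The values are log2 levels per probe set in the table the authors deposited for the whole series, and all 18 of its sample columns matched a sample by name. Per the labels, the arrays are Affymetrix ATH1 arrays, and the authors kept only probes whose sequence is the same in both genomes and matches a representative gene model of TAIR10, with at least 3 probes in a probe set. TAIR10 is also the build in the submitters' processing notes. The background correction, the normalization, the summary of probes into probe sets and the software are not given in the sources used here. The array medians lay between 6.05 and 6.17, and the highest value of an array between 14.09 and 14.33, on the log2 scale. The 25th percentile of an array lay between 4.41 and 4.57. The table gives no background or detection measure per probe set, so that a level under these values is not shown to lie above background, and a difference against such a level can understate the real one. The table was used as deposited, with no further normalization and no filter on low values. For arrays, the number of arrays limits the precision.

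Of 19766 probe sets, 11 control probe sets were left out and 19755 were tested. The plan written before the data were examined named all probe sets of the table, and a fit with the controls included was added after seeing the data. The platform annotation named a single gene for 11763 probe sets and several genes for 61, and did not list 7931, which stay unnamed here. A RefSeq table of the assembly TAIR10.1 held the gene of 11718 of these 11763 probe sets. It was used for names and for the order of neighbouring genes, and no coordinates are printed. A symbol other than the locus was given for 1418 probe sets. For 123 genes there was more than 1 probe set, each tested separately.

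A group-means model was fitted to all 18 arrays with limma's lmFit and eBayes, which gave 12 residual and 5.8 prior degrees of freedom. The 10 comparisons were C24 minus Col-0 at each stage, the 3 stage differences within each accession, and the interaction (the 12-13 minus 8-9 days change in C24 minus that in Col-0). Adjusted p-values are Benjamini-Hochberg values over all probe sets of a comparison, with a threshold of 0.05. Each log2 difference is given with its standard error (SE) from the model, and levels are means with the SD of 3 arrays. With 3 arrays against 3, an exact permutation test of a single gene cannot go below 0.1, so limma's adjusted p is used throughout.

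Named genes were chosen by a rule fixed before the data were examined, among probe sets with a single gene. It took the 8 highest and 8 lowest mean differences among genes past the threshold in the same direction at all 3 stages, then the 3 highest and 3 lowest at each stage outside those 16. The plan named only genes not yet named, but IRX15 and AT4G14980, taken at 10-11 days, were taken again at 12-13 days. It also took the 8 highest and 8 lowest changes from 8-9 to 12-13 days in each accession, the 3 highest and 3 lowest of each adjacent step, and the 6 highest and 6 lowest for the interaction. Except for the interaction, all 3 arrays of a group had to lie above all 3 of the other. From each fixed gene list, up to 4 members past the threshold were eligible for naming in a comparison. Members of the added lists were chosen after their values were seen.

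Before the data were examined, 16 lists were fixed with 309 genes, of which the annotation named only 47. Only 6 of these lists had the 3 named genes needed for a test, and 2 had none. A further 17 lists were formed from gene symbols after the table of gene names had been seen and before any test. A planned list of ribosomal proteins was void, since the annotation holds no gene descriptions. The 23 lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The p-values were adjusted over the 230 tests of lists and comparisons. With the preset correlation 51 tests passed, and 2 of them also passed with an estimated one.

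The model was tested on simulated data with 100 probe sets changed by each size among 19755. For the accession difference at 8-9 days it recovered 97% of changes of 1 log2 unit and 67% of changes of 0.5, with 5.7% of its calls false. For the change from 8-9 to 12-13 days in Col-0 it recovered 97% and 65%, with 6.9% false. For the interaction it recovered 91% and 26%, with 5.6% false. Apart from these changes, all groups had the same simulated means, with independent normal noise and no shared plants. Far fewer probe sets were changed than passed in the real comparisons, so these shares need not hold for the real data.

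The alternatives set before the data were examined were a fit to the compared groups alone, a trended and robust prior variance, a second quantile normalization, centring of each array on its median, removal of the dimmest 30% of probe sets by mean level, array weights, the replicate number as a block, and leaving out each array in turn. A planned change of scale did not apply, since the table is on the log2 scale. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.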

Results

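Transcript levels were measured with ATH1 arrays in developing seeds of Col-0 and C24, natural accessions of Arabidopsis thaliana, at 8-9, 10-11 and 12-13 days after flower opening. Each of the 6 groups held 3 arrays, each made from a pool of seeds, and 19755 probe sets were tested. Differences are log2 values with the SE of the model (n = 3 arrays per group), and adjusted p-values are from limma. Arrays of the same group correlated across probe sets at 0.992 to 0.997, and arrays of different groups at 0.859 to 0.985.

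The first principal component held 73.2% of the variance and ordered the arrays by stage, and the second held 9.8% and separated the accessions. On the first component the arrays at 8-9 days lay at -81.0 ± 2.4 in Col-0 and -71.7 ± 2.9 in C24 (mean ± SD, n = 3). At 10-11 days the C24 arrays lay at 25.2 ± 2.8 and the Col-0 arrays at 7.1 ± 8.4. At 12-13 days the means were 59.9 in C24 and 60.6 in Col-0.

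**Figure D1:**
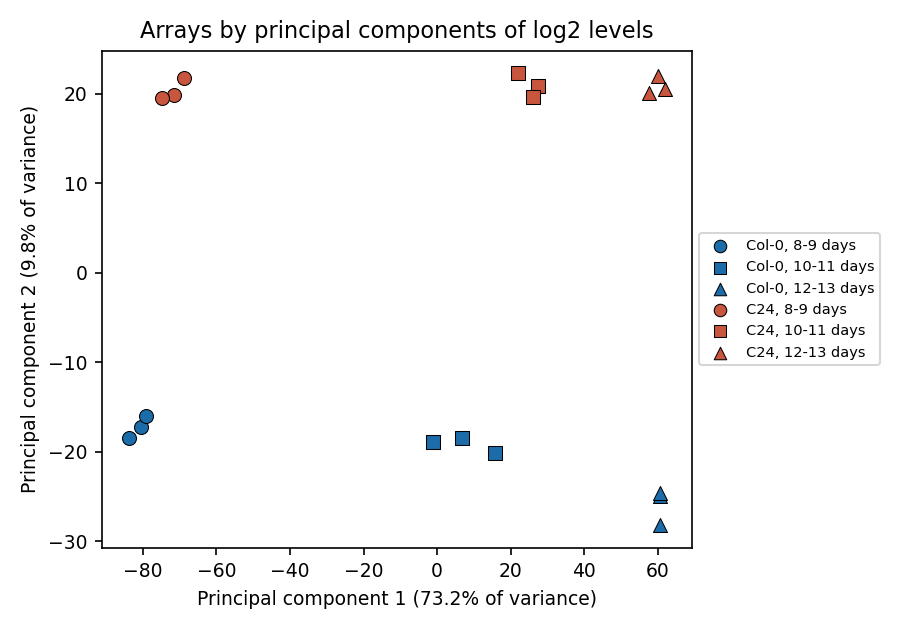
Each point is an array, placed by its scores (arbitrary units) on the first principal component (horizontal, 73.2% of variance) and the second (vertical, 9.8%) of the log2 levels; colours mark accessions and shapes mark stages. Stages follow each other from left to right, with C24 above 0 and Col-0 below 0 on the vertical axis.

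The comparison of 12-13 with 8-9 days asked how transcript levels changed while seeds developed. All 5 named seed storage protein genes rose in both accessions, among them AT1G03890 by 4.21 ± 0.36 in Col-0 and 2.48 ± 0.36 in C24, and PAP85 by 1.65 and 1.39. Both lay at 13.27 to 13.59 at 12-13 days, near the array maxima of 14.09 to 14.33, so that their changes can be understated. The Col-0 arrays of AT1G03890 at 8-9 days were widely scattered, with an SD of 1.23. Its interaction of -1.73 was lost with 8 of 12 arrays left out in turn. It was also lost with a trended and robust prior variance (adjusted p = 0.102) and in a fit to the compared groups alone (0.085). Without replicate 2 of Col-0 at 8-9 days the interaction was -1.02. Of 12 genes for late embryogenesis abundant (LEA) and desiccation proteins, which protect drying cells, 10 rose in each accession, AT3G15670 by 7.15 ± 0.24 in Col-0 and 6.74 in C24. Photosynthesis and cell division genes fell: the change was -2.80 ± 0.11 in Col-0 and -2.87 in C24 for LHCB4.1, a light-harvesting protein, and -3.39 ± 0.14 and -3.21 for AUR1, an Aurora kinase of mitosis. The 3' minus 5' signal of some control probe sets, a sign of RNA quality, moved as well. For a GAPDH control it went from 0.29 to 1.21 in Col-0 and from 0.54 to 0.57 in C24. For an actin control it went from 1.89 to 1.34 in Col-0 and from 2.02 to 1.20 in C24. A second GAPDH control went from 0.15 to 0.45 in Col-0 and from 0.27 to 0.18 in C24. A second actin control went from 1.87 to 1.73 in Col-0 and from 1.85 to 1.42 in C24.

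Of 30 genes for photosystems, the Calvin cycle and chlorophyll synthesis, 27 fell and 1 rose in Col-0, and 28 fell and 1 rose in C24 (adjusted p = 1.32e-10 and 1.27e-11, or 0.0769 and 0.0684 with an estimated correlation). The changes were -4.09 and -3.24 for PORB, an enzyme of chlorophyll synthesis, and 0.49 and 0.50 for PSB27, the gene that rose. The 3 named genes of the fixed photosynthesis list, LHCB4.1, RCA and PRK, fell in both accessions (adjusted p = 0.018 and 0.00968, or 0.244 and 0.221 with an estimated correlation). Of 29 mitosis and DNA replication genes 27 fell in each accession (adjusted p = 9.37e-09 and 3.37e-09, both 0.0538 with an estimated correlation), with -3.50 and -3.44 for PRL, a subunit of the replicative helicase. In the fixed cell cycle list AUR1, AUR2 and PRL fell in both accessions (adjusted p = 0.016 and 0.0176, both 0.291 with an estimated correlation).

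The LEA list had adjusted p = 8.65e-06 in Col-0 and 3.11e-05 in C24, or 0.267 and 0.291 with an estimated correlation. The storage protein list had adjusted p = 0.0106 and 0.0254, or 0.334 and 0.376 with an estimated correlation, and in C24 it missed the threshold after a second quantile normalization (adjusted p = 0.0559) and without the dimmest 30% of probe sets (adjusted p = 0.0603). Adjusted over the list alone, 11 LEA genes rose in each accession, and the counts of the other fixed lists were those given here. All 8 genes for ATG8 proteins, which act in autophagy, rose in both accessions, ATG8E by 2.37 and 2.32 (adjusted p = 0.000327 and 0.000592, both 0.304 with an estimated correlation).

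Lists with fewer named genes were described by their members. BAN and DFR, enzymes of the flavonoid pathway of the seed coat, fell in both accessions, with changes of -4.34 ± 0.16 in Col-0 and -2.65 in C24 for BAN. Both mucilage genes fell, with -2.08 and -1.90 for ARA12 and -3.55 and -1.76 for AT3G50990. The starch enzymes SBE2.2 and DPE1 fell, with -1.51 and -1.95 in Col-0 and -1.30 and -1.92 in C24. Both regulators of maturation, EEL and BZIP53, rose, by 1.22 and 0.84 in Col-0 and by 1.15 and 0.89 in C24, and HSA32 of the heat shock list rose by 1.47 and 1.45. In the glucosinolate list AOP3 rose by 0.76 and 0.70, and AT2G25450 fell, with -1.51 and -2.47. The oleosin gene OLEO3 fell in Col-0 (-0.42), and its change of -0.13 in C24 did not pass; it lay at 12.95 to 13.63 in all groups, near the array maxima of 14.09 to 14.33, so that its differences can be understated. Of 5 fatty acid genes FATB and FaTA rose in Col-0, by 0.85 and 0.30, and AT5G10160, AT2G22230 and AT1G24360 fell, with -1.77, -1.10 and -1.07 (adjusted p = 0.357 for the list). Of 3 endosperm genes AGL62 rose in Col-0, by 0.39 (adjusted p = 0.779 for the list). AGL62 lay at 3.52 to 3.91 in all groups, below the lowest 25th percentile of 4.41, and is not shown to lie above background.

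Among probe sets with a single named gene, AT4G38080 had the highest fitted change in both accessions, 8.81 ± 0.11 in Col-0 and 8.29 ± 0.11 in C24, from a level of 3.94 ± 0.06 to 12.75 ± 0.10 in Col-0 (SD, n = 3). AT1G19900, AT3G60730, AT3G04170, AT2G22510 and AT1G68850 were also among the 8 highest in both, with changes from 7.59 to 8.45. CYP78A9, a cytochrome P450, rose by 8.21 and AT2G18370 by 7.89 in Col-0, and AT1G14940 and AT3G58550 by 7.63 and 7.47 in C24. GILT had the lowest fitted change, with -8.82 ± 0.37 and -8.97 ± 0.37, followed by ATPMEPCRD with -7.23 and -7.34. JMT, a jasmonic acid methyltransferase, changed by -6.61 in Col-0, next in order, and by -5.99 in C24, where it came after AT5G60630. AT4G15750, AT5G15180 and AT5G60630 were among the 8 lowest in both accessions, AT1G56100 and AT1G50650 in Col-0, and AT5G51950 and AT5G48490 in C24. Of these 20 genes 8 had a mean below 4.41, the lowest 25th percentile of an array, in at least 1 of the 6 groups, AT4G38080 among them, so that their changes can be understated and their order is not settled.

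In Col-0 11975 probe sets passed the threshold, 5955 higher and 6020 lower at 12-13 days, and 3528 of them by 2-fold or more. In C24 11729 passed, 5812 higher and 5917 lower, and 3209 by 2-fold or more. Higher in both accessions were 4569, where independent lists would share 1752, and lower in both were 4981, against 1803.1. The changes correlated across probe sets at r = 0.928 (Spearman's rho 0.882), with no array in common. Probe sets are not independent replicates, so no p-value is given for correlations across them.

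From 8-9 to 10-11 days, 24 of 29 mitosis and DNA replication genes fell in Col-0 and 26 in C24, with changes of -2.40 ± 0.14 and -2.83 for AUR1 and of -2.01 and -2.58 for HTB2, a histone H2B. These list results passed with an estimated correlation too (adjusted p = 4.73e-11 and 6e-11, both 0.04 with an estimated correlation). All 5 storage protein genes rose in this step, AT1G03890 by 4.1 and 2.44 (adjusted p = 0.000756 and 0.0163, or 0.291 and 0.355 with an estimated correlation). AT1G03890 reached 13.40 in Col-0 and 13.55 in C24, near the array maxima, so that its changes can be understated. Its Col-0 arrays at 8-9 days were widely scattered, with an SD of 1.23. LEA genes rose too, 9 of 12 in Col-0 and 8 in C24 (adjusted p = 2.32e-05 and 0.000345, or 0.291 and 0.305 with an estimated correlation). Adjusted over the list alone, the LEA counts were 10 and 8. Of 30 photosynthesis genes 24 fell in Col-0 and 27 in C24 (adjusted p = 1.01e-07 and 5.64e-10, or 0.144 and 0.0802 with an estimated correlation).

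The highest single changes of this step were those of AT4G38080, AT1G19900 and AT2G22510 in Col-0 (8.50, 7.98 and 6.99) and of AT4G38080, AT2G22510 and AT1G68850 in C24 (8.64, 7.64 and 7.53). AT4G15750, JMT and GILT had the lowest changes, with -5.69, -4.95 and -4.56 in Col-0 and -4.91, -4.85 and -5.53 in C24. Of the 15 genes named for this step and the next, 4 had a mean below 4.41 in a compared group, AT4G38080 among them. Their changes can be understated, and their order is not settled. In Col-0 8548 probe sets passed, 3941 higher and 4607 lower, and in C24 9874, 4745 higher and 5129 lower.

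From 10-11 to 12-13 days, 24 of 30 photosynthesis genes fell in Col-0 and 22 in C24, with changes of -2.24 ± 0.14 and -1.84 for CaS, a calcium sensor of the chloroplast (adjusted p = 5.45e-12 and 1.65e-11, both 0.0684 with an estimated correlation). LEA genes rose in 9 of 12 cases in Col-0 and 8 in C24, AT3G15670 by 2.59 and 2.31 (adjusted p = 8.65e-06 and 2.32e-05, or 0.267 and 0.291 with an estimated correlation). Adjusted over the list alone, these counts were 10 and 8. None of the 5 storage protein genes passed, also adjusted over the list alone (adjusted p = 0.782 and 0.599 for the list). AT1G03890, PAP85 and AT2G28490 already lay at 13.40, 13.26 and 13.08 in Col-0 at 10-11 days, near the array maxima of 14.09 to 14.33, so that a further rise may not have been measurable. Of 29 mitosis and DNA replication genes 10 fell and 1 rose in Col-0 (adjusted p = 0.00881, or 0.291 with an estimated correlation), and 7 fell in C24 (adjusted p = 0.0758). Of 5 fatty acid genes 4 fell in Col-0, with -1.03 for AT5G10160 (adjusted p = 0.0207, or 0.304 with an estimated correlation, and 0.0603 without the dimmest 30% of probe sets).

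FACT, an acyltransferase of wax synthesis, rose by 5.51 ± 0.45 in Col-0 and 4.76 ± 0.45 in C24 in this second step. AT3G58550 and AT1G14940 rose by 5.44 and 5.28 in Col-0, and AT1G54870 and AT3G21380 by 4.76 and 4.65 in C24. GILT and AT1G09750 fell, with -4.26 and -4.01 in Col-0 and -3.44 and -3.22 in C24, as did AT5G15180 in Col-0 (-3.90) and AT5G60630 in C24 (-3.04). In Col-0 7096 probe sets passed, 3478 higher and 3618 lower, and in C24 5085, 2307 higher and 2778 lower. Across probe sets the changes of the accessions correlated at 0.884 in the first step and 0.764 in the second.

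**Figure D2:**
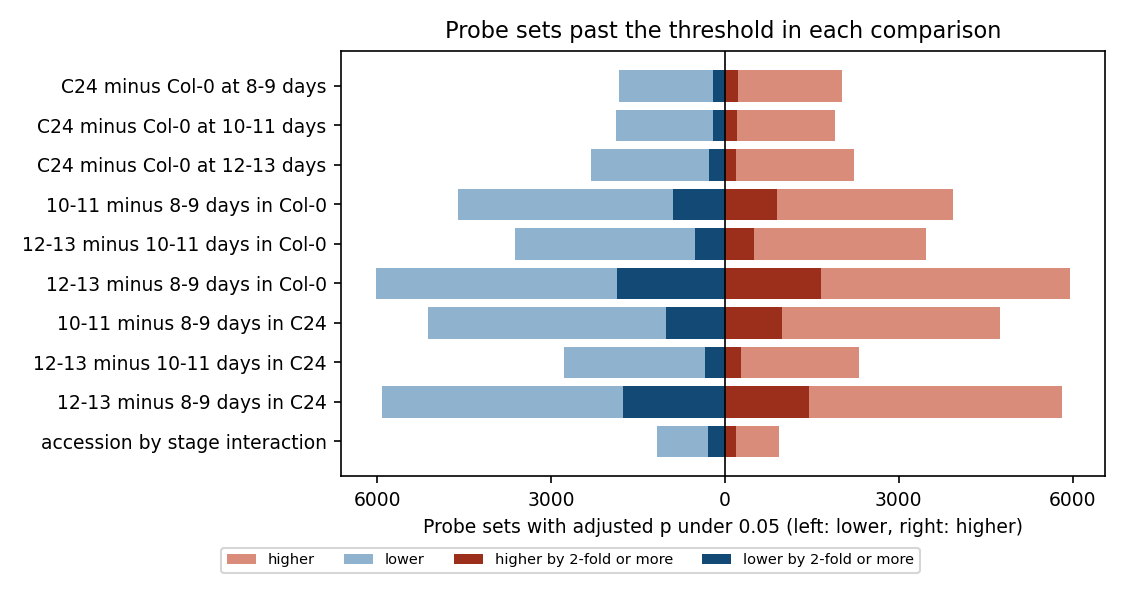
Bars give the number of probe sets with an adjusted p under 0.05 (horizontal) in each of the 10 comparisons (vertical), higher to the right of 0 and lower to the left; dark parts differ by 2-fold or more. The 12-13 minus 8-9 days change in Col-0 has the most, 5955 higher and 6020 lower, and the interaction the fewest, 934 and 1166.

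The comparisons of C24 with Col-0 asked which transcripts differ between the accessions at the same age. AT4G29200 was higher in C24 at every stage, by 6.04 ± 0.15 at 8-9, 5.66 at 10-11 and 5.40 at 12-13 days, with a level of 4.56 ± 0.26 in Col-0 and 10.60 ± 0.07 in C24 at 8-9 days (SD, n = 3). AT2G41650 was lower in C24 at every stage, with differences of -3.88 ± 0.24, -4.81 and -4.60. AT1G02300, AT5G15360, AT5G41250, AT2G15960, AT1G48800, GSTU26 (a glutathione transferase) and AT1G64130 were the next highest, with means over the stages from 3.86 to 2.51. AT1G17860, AT3G04200, AT1G28590, AT3G19520, AT5G51490, scpl42 (a serine carboxypeptidase-like protein) and AT1G03710 were the next lowest, with means from -3.90 to -2.57. In total 533 probe sets were higher in C24 at all 3 stages and 536 lower, against 22 and 20.4 for independent lists. Of the 16 genes named here 5 had a group mean below 4.41, the lowest 25th percentile of an array, so that their differences can be understated. Another 323 passed with opposite signs at different stages.

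At 8-9 days, BAN and DFR of the seed coat were lower in C24, with -0.75 ± 0.16 and -0.85 ± 0.10, as was the mucilage gene AT3G50990 with -1.73. Of 5 storage protein genes AT1G03890 (1.81 ± 0.36), AT2G28490 (0.64) and AT4G36700 (0.34) were higher in C24, and adjusted over the list alone all 5 were (adjusted p = 0.0104, or 0.334 with an estimated correlation). LEA18 was higher by 1.22 ± 0.14, and AT3G17520, LEA and AT4G21020 of the same list of 12 by 0.82, 0.68 and 0.51 (adjusted p = 0.195 for the list; 4 genes also adjusted over the list alone). Without replicate 2 of Col-0 at 8-9 days the difference was 1.11 for AT1G03890 and the calls of AT4G36700, AT3G17520, LEA and AT4G21020 were lost, with 0.23, 0.55, 0.33 and 0.35. These 4 calls were also lost without replicate 1 or replicate 2 of C24 at 8-9 days and in a fit to the compared groups alone, and those of AT4G36700 and AT4G21020 without replicate 1 of Col-0. With a trended and robust prior variance AT3G17520, LEA and AT4G21020 missed the threshold (adjusted p = 0.0595, 0.0678 and 0.063), and AT4G21020 also with a second quantile normalization (0.0515), centred arrays (0.0636) and the replicate number as a block (0.0549).

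Of 47 UDP-glycosyltransferases, which attach sugars to small molecules, 12 were lower in C24 at 8-9 days, with -1.31 for UGT84B1 and -1.04 for UGT84A3, and UGT71C4 was higher by 0.60 (adjusted p = 0.024, or 0.305 with an estimated correlation, and 0.0559 after a second quantile normalization). Of 27 serine carboxypeptidase-like genes 7 were lower, with -1.41 for SCPL45 and -1.13 for SCPL27 (adjusted p = 0.00397, or 0.0769 with an estimated correlation). AT1G62210 (4.30 ± 0.41), AT5G42860 (3.41) and AT2G03980 (3.38) were the highest genes not named above, and AT2G15325 (-4.42), AT2G32190 (-3.83) and AT1G11590 (-3.67) the lowest. The Col-0 arrays of AT1G62210 were widely scattered here, with an SD of 1.47. At this stage 3847 probe sets passed, 2025 higher and 1822 lower in C24, 436 of them by 2-fold or more.

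At 10-11 days, 11 of 30 photosynthesis genes were lower in C24, with -0.70 ± 0.12 for HEME2, an enzyme of porphyrin synthesis, and -0.61 for LHCB4.2, and PGRL1B was higher by 0.38 (adjusted p = 0.000369, or 0.304 with an estimated correlation). In the fixed list of 3 photosynthesis genes LHCB4.1 (-0.58) was lower, and adjusted over the list alone 2 were (adjusted p = 0.114 for the list). AUR1 (-0.82) and AUR2 (-0.30) of 3 cell cycle genes were lower, and all 3 adjusted over the list alone (adjusted p = 0.0269, or 0.304 with an estimated correlation). The list of 29 mitosis and DNA replication genes did not pass, with 6 lower and 2 higher (adjusted p = 0.0517, or 0.356 with an estimated correlation). ATG8E (0.68), ATG8D (0.64) and ATG8C (0.47) of 8 ATG8 genes were higher (adjusted p = 0.018, or 0.409 with an estimated correlation). On the first principal component the arrays of these groups lay at 25.2 in C24 and 7.1 in Col-0. Without replicate 2 of Col-0 at 10-11 days the adjusted p was 0.0509 for the cell cycle list, 0.0555 for the ATG8 list and 0.0771 for AUR2. AUR2 also missed the threshold without replicate 1 of Col-0 and without replicates 1 and 3 of C24 at this stage (adjusted p = 0.0803, 0.0845 and 0.0609), and the cell cycle list without the dimmest 30% of probe sets (0.0522).

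Among genes not named above for all stages, IRX15, which acts in xylan synthesis of secondary walls, was the highest at 10-11 days, 4.06 ± 0.12 higher in C24. Next among these were NRPC2, a subunit of RNA polymerase III, at 2.97 and AT2G23400 at 2.95. AT4G14980 (-3.05), AT3G19515 (-2.84) and AT1G35612 (-2.60) were lower. AT2G25450 of the glucosinolate list differed by -1.20, -2.19 and -2.15 at the successive stages. At 10-11 days 3783 probe sets passed, 1898 higher and 1885 lower in C24, 414 of them by 2-fold or more.

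At 12-13 days, BAN was 0.95 ± 0.16 higher in C24, OLEO3 0.44 higher (near the array maxima, where it can be understated), BZIP53 0.36 higher and HSA32 0.34 higher, while RCA, the activase of Rubisco, differed by -0.73 and the LEA gene AT3G53040 by -0.84. None of the lists passed the threshold in this comparison. The 3' minus 5' signal of GAPDH controls, a sign of RNA quality, differed between the accessions at this stage by -0.63 ± 0.16 and -0.27 ± 0.11 (SE) in 2 control sets. IRX15 was 4.45 ± 0.12 higher in C24, AT5G38780 3.95 and AT2G27570 3.43, and AT5G51500 (-4.12), AT2G23110 (-4.04) and AT4G14980 (-3.83) were lower. Of the 16 genes named for a single stage 9 had a mean below 4.41 in an accession at that stage. Past the threshold were 4547 probe sets, 2232 higher and 2315 lower in C24, 463 of them by 2-fold or more. The accession differences correlated across probe sets at 0.526 between 8-9 and 10-11 days, 0.619 between 10-11 and 12-13 days, and 0.459 between 8-9 and 12-13 days.

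**Figure D3:**
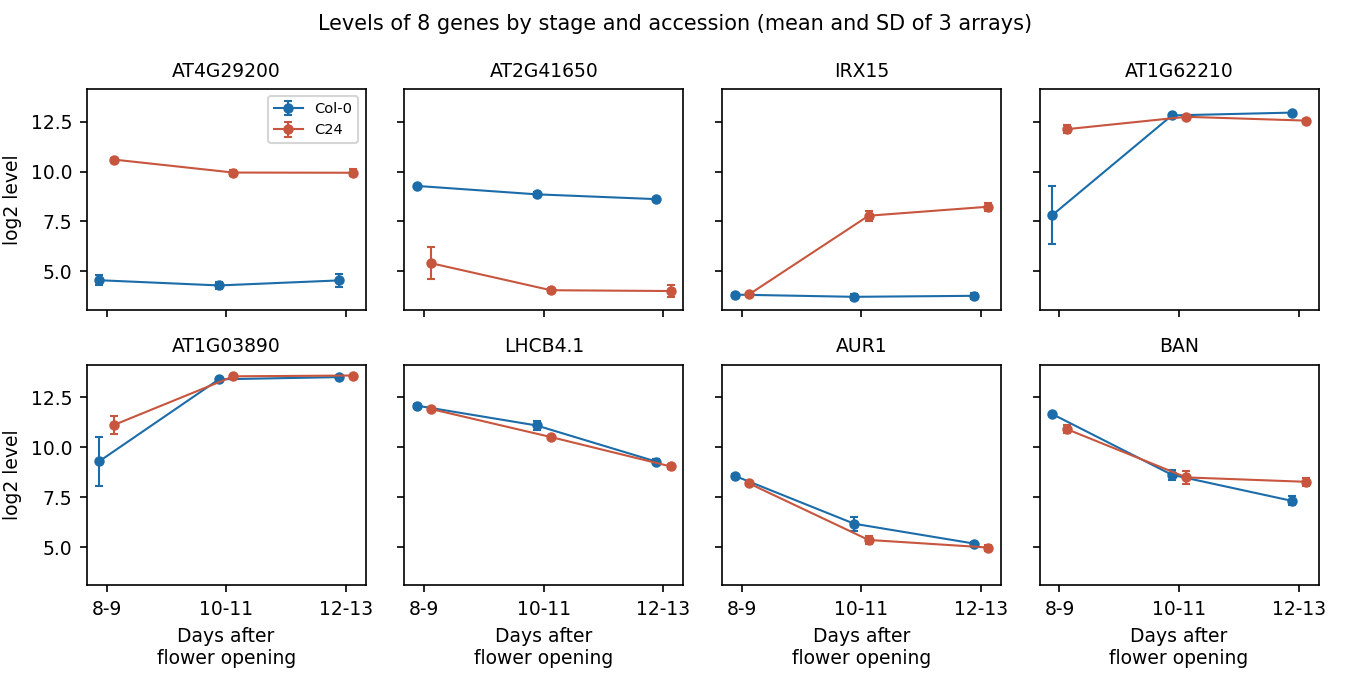
Log2 levels (vertical) of 8 named genes at 3 stages (horizontal, days after flower opening) in Col-0 and C24; points are means and bars the SD of 3 arrays. AT4G29200 and AT2G41650 lie apart between the accessions at all stages, IRX15 is 4.45 higher in C24 at 12-13 days, and LHCB4.1, AUR1 and BAN fell in both.

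The interaction asked which genes changed from 8-9 to 12-13 days by different amounts in the accessions. IRX15 rose by 4.39 in C24, against -0.05 in Col-0, a difference of 4.44 ± 0.17. LCR67, a defensin gene, rose by 3.12 in C24, against 0.07 in Col-0, and AT1G62210 rose by 5.14 in Col-0, against 0.43 in C24. At 8-9 days AT1G62210 lay at 7.82 ± 1.47 in Col-0 and 12.12 ± 0.20 in C24 (SD, n = 3), so that its difference rests on a scattered group. The seed coat genes BAN, DFR and AT3G50990 fell less in C24, with differences of 1.7 ± 0.23, 0.72 and 1.79. DFR and AT3G50990 started lower in C24 at 8-9 days, at 10.02 against 10.87 and 6.51 against 8.24 in Col-0. They ended at similar levels at 12-13 days, 8.37 and 8.50 for DFR and 4.75 and 4.70 for AT3G50990. Their differences thus mainly restate those at 8-9 days, and AT3G50990 ended near 4.41, where a further fall may not have been measurable. BAN ended higher in C24, at 8.27 against 7.32. IRX15 lay at 3.84 and 3.78 in Col-0 and started from 3.85 in C24. Of the 12 genes named for the interaction 8 had a group mean below 4.41. A change below background would be missed in these 8 genes, so that their differences can be understated or overstated. The 3' minus 5' signal of a GAPDH control went from 0.29 ± 0.16 to 1.21 ± 0.27 in Col-0 and from 0.54 ± 0.36 to 0.57 ± 0.07 in C24 (SD, n = 3) over these stages. In all 2100 probe sets passed, 934 with a higher and 1166 with a lower change in C24, 484 of them by 2-fold or more.

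Of 7 flavonoid enzymes BAN, DFR and UF3GT had a higher change in C24 (adjusted p = 0.0353, or 0.221 with an estimated correlation). Of 12 LEA genes AT3G53040 (-1.11 ± 0.23) and LEA18 (-1.09) had a lower change, and 3 adjusted over the list alone (adjusted p = 0.0387, or 0.512 with an estimated correlation). The flavonoid result missed the threshold without replicate 2 of Col-0 at 12-13 days (adjusted p = 0.0819) and without replicate 1 of C24 at 8-9 days (0.0508). The LEA result missed it without the dimmest 30% of probe sets (0.079) and without replicate 2 of Col-0 at 8-9 days (0.117), replicate 3 of Col-0 at 12-13 days (0.13), replicates 1 and 2 of C24 at 8-9 days (0.0849 and 0.135) and replicate 2 of C24 at 12-13 days (0.102).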

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

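Of the tests below, those on probe sets with a mean 4-fold higher in C24, on single arrays of the 10-11 day groups and on neighbouring genes at single stages were chosen only after results were seen.

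The 12 genes listed here drew attention because their change from 8-9 to 12-13 days differed between the accessions in the interaction test, and they are the 6 highest and 6 lowest of the 1128 with a single named gene among 2100 probe sets that passed it. In 8 of them a group mean lay below 4.41, the lowest 25th percentile of an array. A change below background would be missed in these 8 genes, so that their differences can be understated or overstated. IRX15 rose by 4.39 in C24 against -0.05 in Col-0, a difference of 4.44 (adjusted p = 7.55e-12). AT5G38780 rose by 3.73 against 0.04 (difference 3.69, adjusted p = 9.73e-09), AT2G27570 by 4.23 against 0.85 (3.38, 1.23e-12) and LCR67 by 3.12 against 0.07 (3.06, 4.55e-07). AT2G15325 changed by -0.28 in C24 and -4.10 in Col-0 (difference 3.82, adjusted p = 1.46e-05), and AT1G11590 by 0.01 and -3.59 (3.60, 4.28e-12). AT1G62210 changed by 0.43 in C24 and 5.14 in Col-0 (difference -4.70, adjusted p = 2.65e-05), AT2G43535 by -0.23 and 4.13 (-4.36, 2.53e-09) and AT5G41250 by -4.20 and 0.01 (-4.22, 1.37e-09). The Col-0 arrays of AT1G62210 at 8-9 days were widely scattered, with an SD of 1.47. AT2G23110 changed by 1.25 in C24 and 5.16 in Col-0 (difference -3.91, adjusted p = 1.9e-08), AT5G51500 by 0.60 and 4.26 (-3.65, 4.52e-08) and AT4G14980 by 0.31 and 3.70 (-3.39, 1.44e-10).

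Each accession's mean level was first removed from every probe set. Of 100 splits that then exchanged accession labels within 8-9 and within 12-13 days, 1, the real one, gave as many interaction calls as the 2100 found. The highest other gave 394, so that the count was beyond that of the other groupings drawn. Groups mixed by the exchange carry real differences in their spread, which lowers their counts. Pools shared plants and their batches were not known, so the splits cannot exclude differences between plants or batches. For the other 9 comparisons the 10 splits are too few for a share under 0.05. Their other splits mixed arrays of both groups, so that real differences entered the spread and lowered the counts. These low counts therefore do not measure calls made by chance. The real counts at 8-9, 10-11 and 12-13 days between accessions were 3847, 3783 and 4547, and the highest other splits gave 1, 1 and 0. For the steps 10-11 minus 8-9, 12-13 minus 10-11 and 12-13 minus 8-9 days they were 8548, 7096 and 11975 in Col-0, with 1, 0 and 0 in the highest other split, and 9874, 5085 and 11729 in C24, with 0 in each.

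A first pattern is the set of 43 probe sets past the threshold in 1 direction at all 3 stages with a mean difference of 4-fold or more, AT4G29200 and AT2G41650 among them. Of these 21 were higher in C24, which a residual mismatch of probes to the C24 sequence cannot give, since it would lower C24. For the 22 that were lower in C24, 51.2% of the 43, with an exact 95% interval from 35.5 to 66.7, such a mismatch cannot be told apart from a lower level, although the authors, per the labels, kept only probes with the same sequence in both genomes, since no C24 sequence was at hand to check that filter. In 20.9% of the 43 the lower accession lay below the 25th percentile at all 3 stages, with an exact 95% interval from 10 to 36, but the table has no detection measure and levels just above that percentile are not shown to be expressed, so that silent genes stay open too. A difference in regulation between the accessions was not tested.

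A second pattern is that the accession difference at 10-11 days ran along the change from 8-9 to 12-13 days (r = 0.335 across probe sets), and of the 2511 calls at that age that were also called for this change in both accessions 78.8% had its direction. At 8-9 and 12-13 days r was 0.039 and -0.042 along other changes, 12-13 minus 10-11 and 10-11 minus 8-9 days, chosen to share no array, so that the 3 values cannot be ranked. At 10-11 days the list of photosystem, Calvin cycle and chlorophyll synthesis genes and the cell cycle list were lower in C24. The ATG8 list was higher. These were the directions of their changes with stage, but none of these lists passed with an estimated correlation. The fixed photosynthesis list, the mitosis and DNA replication list and the storage protein list did not pass. C24 seeds further advanced at this age may account for the pattern. The LEA list did not pass at 10-11 days (adjusted p = 0.578), so that this stays open. The lowest value with an array left out was 0.257, without replicate 2 of Col-0, above 50% of the full value, which argues against a single array as the whole source, although it lies under 0.3. RNA quality stays open, since the largest accession difference of the 3' minus 5' control signal at 10-11 days was 0.34 (SE 0.25), too uncertain to exclude 0.5. At 8-9 days C24 also lay further along the first principal component (-71.7 ± 2.9, against -81.0 ± 2.4 in Col-0, SD). An advance of C24 at that age was not tested along the step from 8-9 to 10-11 days and stays open.

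Another pattern concerns neighbouring genes called in the same direction between accessions. For calls held at all 3 stages there were 21 such pairs, 1.22 times the mean of 10000 shuffles and under their 95th percentile of 24 by less than their SD of 4.1, so that a shared difference of neighbours stays open there. At single stages there were 221, 246 and 324 pairs at 8-9, 10-11 and 12-13 days, above the 95th percentiles of 218, 218 and 301 and 1.12, 1.25 and 1.17 times the means, which is consistent with neighbours differing together. Calls for 12-13 minus 8-9 days exceeded theirs too, with 1989 pairs against 1984 in Col-0 and 1962 against 1940 in C24, 1.03 and 1.04 times the means. Cross-hybridisation of tandem copies was not tested and stays open.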

How the results depend on the processing

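The fit with control probe sets included was chosen after seeing the data; the other alternatives were planned. All 10 counts of calls stayed within 1.5 times under every alternative run, with 1.37 as the largest ratio, and no split of higher and lower calls moved by over 10 percentage points. With an array left out, the count at 8-9 days ranged from 2814 to 3698 between accessions, and the interaction from 1634 to 2116. The correlation of stage changes was 0.9362 without the dimmest 30% of probe sets, beyond its jackknife SE of 0.00694; fewer probe sets were compared there. Centring arrays on their medians moved the median change from 8-9 to 12-13 days in C24 from 0.027 to 0.108. The 51 list calls were tested again under the alternatives. Of these repeated tests, 12 of 306 were lost under other settings and 16 of 318 with an array left out. With an estimated correlation only 2 of the 51 list calls remained. Interactions that did not pass the threshold changed sign with an array left out for EEL (range -0.216 to 0.048), with 0.002 without replicate 2 of Col-0 and 0.048 without replicate 1 of C24 at 8-9 days, and for BZIP53 (highest 0.099), with -0.016 without replicate 1 of Col-0 at 12-13 and -0.014 without replicate 3 of C24 at 8-9 days; the cause was not tested. No pairing by replicate number was seen. Of 45 pairs with the same number 6 had correlated deviations over 0.1 (median 0.016), and 4 of 18 arrays correlated best with their own number. Weak correlations cannot exclude that samples were paired by plant or experiment. With the replicate number as a block the counts were 3780 at 8-9 days between accessions and 2076 for the interaction.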

Other observations

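The lists described here were formed after the gene names and before any test, and their members were chosen after their values were seen. From 8-9 to 12-13 days 15 of 35 AGAMOUS-like factors rose in C24 and 1 fell, AGL67 by 4.08 ± 0.13 (adjusted p = 0.0483, or 0.344 with an estimated correlation), against 14 and 2 in Col-0 (adjusted p = 0.143). The C24 result missed the threshold after a second quantile normalization (0.117), without the dimmest 30% of probe sets (0.112), without replicate 1 or 2 of C24 at 8-9 days (0.0734 and 0.0549) and without replicate 1 or 2 of C24 at 12-13 days (0.0555 and 0.0529). SDP1 and FAAH of 5 lipid mobilisation genes were higher in C24 at 8-9 days, by 0.57 and 0.56 (adjusted p = 0.0387, or 0.334 with an estimated correlation). That list missed the threshold in a fit to the compared groups alone (0.0557), without replicate 2 of Col-0 (0.0928) and without replicates 1 and 2 of C24 at 8-9 days (0.0641 and 0.0814). Of 10 LEA and cold-induced genes named by the annotation 5 rose in Col-0 and 1 fell (adjusted p = 0.039, or 0.334 with an estimated correlation, and 0.051 after a second quantile normalization), and in C24 5 rose and 1 fell too, but the list did not pass (adjusted p = 0.114, or 0.429 with an estimated correlation).

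No list test passed in any comparison for the following groups, given for 12-13 minus 8-9 days in Col-0. SWEET transporters rose in 9 of 14 cases and fell in 3 (adjusted p = 0.251), and expansins and related wall enzymes in 12 and 12 of 41 (0.958). Of 20 beta-glucosidases 8 rose and 3 fell (0.236), of 13 glutathione transferases 2 rose and 5 fell (0.414), and of 16 probe sets for 15 citric acid cycle genes 1 rose and 9 fell (0.183). Among 13 thionins and defensins 5 rose and 3 fell (0.993). Markers of other tissues were tested too: 5 of 16 fruit, leaf and stomatal regulators rose and 2 fell (0.429), and of 15 probe sets for 14 pollen and anther genes 5 rose and 3 fell (0.9). FMA, a guard cell regulator, rose by 0.24 in Col-0 and 0.29 in C24, the first lost without replicate 2 of Col-0 at 8-9 days (adjusted p = 0.0655). FMA lay at 3.80 to 4.15 in all groups, below the lowest 25th percentile of 4.41, and is not shown to lie above background. ALC, a fruit regulator, changed by -0.36 in Col-0, a call lost with 4 of the 6 arrays left out in turn (adjusted p from 0.0564 to 0.16) and with array weights (0.0575). The change was only -0.23 without replicate 2 of Col-0 at 12-13 days.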
